A study of Mus musculus with 12 samples.

How the data were processed

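Expression was measured by RNA sequencing of mouse bone marrow hematopoietic stem cells (strain C57BL/6). Per the labels' protocols, 50 cells per library were sorted by FACS into lysis buffer, amplified directly with Smart-Seq2, a full-length cDNA method without molecular identifiers, sonicated, ligated to adapters, amplified again by PCR and size-selected on a gel. Cells came from mice of 2 months (young) or 28 months (old) and were sorted as negative or positive for the surface receptor IL27RA, which gave 4 groups of 3 libraries. The gates that define a stem cell are not given in the sources used here. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. One label of old IL27RA− replicate 1 calls it young. Its title and its age of 28 months say old, and it was placed in the old group.

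Per the submitters' processing notes, the tools named are FastQC 0.11.5, TopHat2 2.1.1, HTSeq and DESeq2, with no role or order. The genome build is not given in the sources used here, and no coordinates were used. The deposited table holds log2 values, per gene and library, which from the values are log2 of the read count divided by a size factor, plus a pseudocount of 1. Dividing out the size factor gave whole reads for 100% of the values, within a tolerance of 0.001 reads. The table pairs each Ensembl gene identifier with a symbol. Of 20473 lines, 1 damaged line (the gene Mtbp) and 15 repeats of genes were left out, which left 20457 genes, and 21 names that a spreadsheet had turned into dates were restored. Of these genes, 19007 (92.9%) were matched by identifier to the GENCODE mouse annotation, which was used for biotypes and names only.

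Libraries held 11669083 to 24153167 reads in genes, and between 13509 and 15955 genes had a read. Normalized counts are 2 to the power of the deposited value, minus 1. A floor of 3 reads in a library corresponds to 1.93 to 3.77 normalized counts, depending on the library. Intervals and floors cover counting error only, because amplified reads are not independent molecules. Library values correlated with r between 0.786 and 0.869 within groups and between 0.752 and 0.863 across groups, so no library was a repeat of another.

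The main test was limma 3.58.1 (R 4.3.3) with a variance trend, fitted to the deposited log2 values of all 12 libraries with 1 mean per group. It has 8 residual degrees of freedom and 6.58 prior ones, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Genes entered when at least 3 of the 12 libraries reached 10 on the linear scale, which 14803 genes did. Differences are on the log2(normalized count + 1) scale, which understates changes of low genes. The comparisons were IL27RA+ minus IL27RA− within young and within old cells, old minus young within each sorted fraction, the average of each pair, and the difference between the pair (the interaction). These tests assume log2 values. The plan expected log2 values and named a count tool only in case the table held raw counts, so no count tool was run. Limma voom on the recovered reads was added as an alternative after the data were seen.

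Gene lists for stem cells, lineages, pathways and other cell types of the marrow, 27 in all, were fixed before the data were examined, as were the design, the alternatives and the rule for named genes. Of these lists, 25 with at least 5 members past the filter were tested with camera at a preset correlation of 0.01, and the 175 tests were adjusted together. Tests with an estimated correlation are reported beside them, and fry as a count of called tests, by name where it called a list that camera did not. Of these tests 51 were called with the preset correlation, and only 5 of them with an estimated one. These were the aged stem cell list in 3 age comparisons, the cell cycle list in old IL27RA+ against old IL27RA− cells, and the stem cell identity list in the averaged IL27RA comparison. The neutrophil list (4 members past the filter) and the mast cell and basophil list (2 members) were not tested.

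Named genes were Il27ra, the 10 largest differences in each direction among called genes whose groups did not overlap (for averages, genes with the same sign in both strata), and the 4 members of each described list with the smallest p. Predicted genes were left out. Where fewer than 5 genes were called, the 5 with the smallest p in each direction are given as values. The fit was tested on counts simulated from the 14803 genes. The changed genes were drawn from those with a read in all 12 libraries. The shares recovered therefore do not cover genes with no or almost no reads in a group. For old against young IL27RA+ cells it recovered 47% of genes changed by 4-fold and 86% of those changed by 16-fold, with 6 false calls. For the averaged age comparison it recovered 73% and 97%, with 10 false calls. In a separate draw of this kind, camera found a list shifted by 1 on the log2 scale in old IL27RA+ cells and called 0 of 168 other tests. Genes were simulated independently of each other, so this does not measure false calls among correlated genes.

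The alternatives were filters, variance models, library weights, scalings, a pseudocount of 8, a fit of only the groups compared, a replicate block, each library left out in turn, voom, and a fit without the 2 libraries with the lowest weights. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for reading and plotting.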

Results

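The series profiled hematopoietic stem cells from young (2 months) and old (28 months) mouse bone marrow, each sorted into cells without and with IL27RA, the receptor subunit for the cytokine IL27. Each of the 4 groups had 3 libraries of 50 cells. Reads in genes averaged 21.7 ± 2.55 M (SD, n = 3) in young IL27RA− libraries, 13.9 ± 2.42 M in young IL27RA+, 15.3 ± 2.50 M in old IL27RA− and 15.6 ± 1.71 M in old IL27RA+ libraries. Genes with at least 10 normalized counts numbered 12760 ± 557, 13261 ± 343, 13092 ± 339 and 13591 ± 92.5 in the same order. Young IL27RA− replicate 2 (weight 0.436) and old IL27RA− replicate 1 (weight 0.544) lay farthest from their groups. Old IL27RA− replicate 1 also held 312300 normalized counts of the antibody light chain Igkc, 1.82% of its reads, against 18.8 to 248 in the other libraries.

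The sorted receptor's own mRNA did not separate the sorted fractions. Il27ra stood at 1231 ± 456 normalized counts (SD, n = 3) in young IL27RA− and 1088 ± 186 in young IL27RA+ cells, and at 1379 ± 282 and 1294 ± 182 in the old fractions. The IL27RA+ minus IL27RA− difference was −0.11 ± 0.32 (log2, SE) in young cells, with a 95% interval of −0.80 to 0.58 and a limma adjusted p of 0.953. In old cells it was −0.08 ± 0.32, interval −0.77 to 0.61, adjusted p = 1. A two-sided exact permutation test gave p = 0.8 at both ages, where 3 against 3 libraries cannot go below 0.1. Ebi3, which encodes a subunit of the IL27 cytokine, fell with age by 2.59 ± 0.25 (log2, SE) averaged over the fractions (adjusted p = 0.000136), from 1633 ± 170 to 407 ± 103 normalized counts in IL27RA− and from 1984 ± 390 to 231 ± 97.2 in IL27RA+ cells. Its age difference was called in both fractions.

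**Figure D1:**
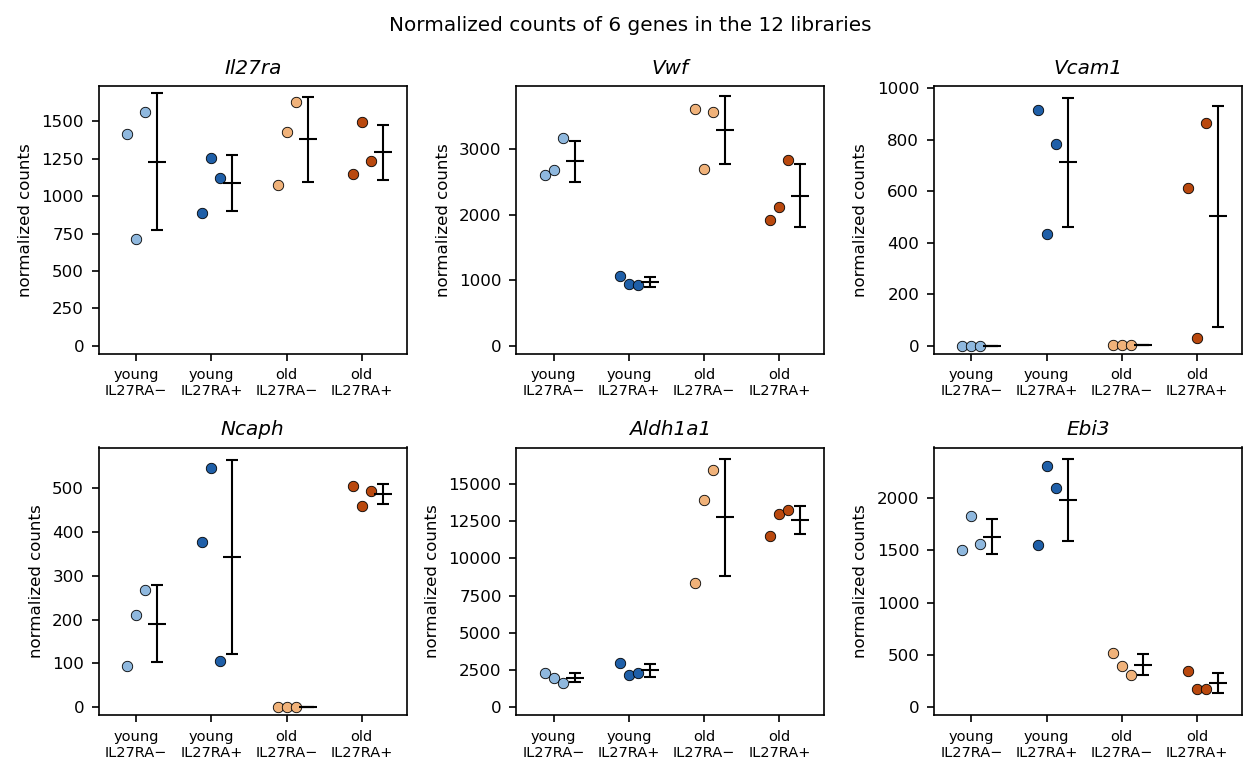
Normalized counts (vertical axes, linear from 0) of 6 genes in each of the 12 libraries, with points for libraries and bars for the mean ± SD of the 3 libraries of a group. Il27ra overlaps between IL27RA− and IL27RA+ libraries, Vcam1 is at about 1 normalized count or less in the IL27RA− libraries, Ncaph is near 0 in old IL27RA− libraries, and Aldh1a1 and Ebi3 separate by age.

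More genes were called between the ages than between the sorted fractions. The ages are different animals, while the fractions may share animals, which the labels do not tell. The counts therefore do not rank the effects of age and sort. Aldh1a1, an aldehyde dehydrogenase, rose in old cells from 1971 ± 310 to 12750 ± 3947 normalized counts (SD, n = 3) in the IL27RA− fraction and from 2485 ± 439 to 12570 ± 949 in the IL27RA+ fraction (averaged log2 difference 2.50 ± 0.17 SE, adjusted p = 6.84e-06). Selp, the adhesion molecule P-selectin, rose from 198 ± 334 and 204 ± 58.4 to 7306 ± 3295 and 5246 ± 939 normalized counts, the scramblase gene Plscr2 from 245 ± 159 and 54.5 ± 43.1 to 5886 ± 1887 and 4798 ± 682, and the oxysterol receptor gene Gpr183 from 14.3 ± 14.4 and 146 ± 204 to 4274 ± 1713 and 2040 ± 922 in the IL27RA− and IL27RA+ fractions. Of the young IL27RA− libraries, replicate 3 held 584 normalized counts of Selp and the others 3.2 and 7.2. Gimap7, a GTPase of the immunity-associated family, fell from 88.4 and 189 to 0 and 0.3 normalized counts, and the cytokine signalling inhibitor Socs2 fell from 1274 and 1064 to 114 and 38. In all, 204 genes were higher and 70 lower in old cells (limma on 14803 genes), and 272 of the 274 had the same sign in both fractions.

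The list of genes known from earlier work to rise in aged stem cells was the most uniform group. Of its 37 measured members, 28 rose over all genes and 37 adjusted over the list alone, with a median difference of 1.99 (camera adjusted p = 5.73e-50, and 0.000254 with an estimated correlation). Its members with the smallest p were Aldh1a1, the chloride channel regulator Clca1 (3.11 ± 0.30), Plscr2 (5.99 ± 0.58) and the LIM protein gene Fhl1 (1.69 ± 0.17). Megakaryocyte and platelet genes also stood higher, with 6 of 28 called, 11 adjusted over the list alone, and a median of 0.72 (adjusted p = 7.65e-07, but 0.139 with an estimated correlation). Sdpr (3.10 ± 0.40), Selp (6.34 ± 0.87), the platelet protein gene Plek (2.60 ± 0.38) and Cd9 (0.71 ± 0.14) led it. Of these, Sdpr, Selp and Cd9 also belong to the aged stem cell list, as do the members Vwf, Itgb3 and Mmrn1. The increases of the lists are therefore not separate results. Other large averaged increases were Zg16, Matn4, Tdrd9, the oncostatin M receptor gene Osmr, Rasef, the complement gene C4b, Rcvrn, Mab21l2 and Gpx8, with differences of 6.96 to 8.42. Other large decreases were Rgs7bp, Haao, the imprinted RNA H19, Zan, Ecm2, Adcy3, Bank1 and AI428936, with differences of −6.36 to −4.24. The count was 431 without young IL27RA− replicate 1, and 140 to 174 without any 1 of the 3 old IL27RA+ libraries or of old IL27RA− replicates 2 and 3.

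In the IL27RA− fraction alone, 76 genes were higher and 23 lower in old cells. Zg16 had 1711 reads in the old libraries and 1 in the young, a depth-adjusted ratio of 2570 (exact 95% counting interval 461 to 102000). Osmr stood at 0.3 and 629 ± 252 normalized counts, the nuclear receptor gene Rorb at 1.4 and 825, and C4b at 0.3 and 322. Ripk4 and Tdrd9 had no reads in young libraries and rose at least 184-fold and 182-fold against a floor of 3 reads per library. Lower in old cells were H19 (604 ± 480 against 0.3), Bmp8a and Plagl1 (204 and 187 against 0), Gimap7, Pdzk1, Adam11 and the growth factor gene Igf1 (815 ± 218 against 85.7 ± 19.1). Of 37 aged stem cell genes, 17 rose, 32 adjusted over the list alone (adjusted p = 1.1e-36, and 0.000393 with an estimated correlation).

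The proliferation genes Ncaph (condensin) and Uhrf1 (maintenance of DNA methylation) also fell with age in IL27RA− cells, from 191 ± 88.7 to 0.4 and from 397 ± 127 to 14.6 normalized counts. Of 47 cell cycle genes, 1 (Uhrf1) fell over all genes, 12 adjusted over the list alone, and 10 had a positive difference (median −1.14, adjusted p = 4.11e-08, but 0.377 with an estimated correlation). Without young IL27RA− replicate 1 the median was −0.64 and the adjusted p 0.0168, and that library stood at 1.17 in the list where the other young IL27RA− libraries stood at −1.46 and −1.74 and the old ones at −2.34 to −1.52. Mcm7 (−1.14 ± 0.25), Cdt1 (−2.60 ± 0.62) and E2f1 (−5.70 ± 1.42) did not pass. Mitochondrially encoded transcripts stood higher, with 2 of 14 called, mt-Atp6 (1.24 ± 0.23) and mt-Nd1 (0.88 ± 0.19), and 8 adjusted over the list alone (median 0.80, adjusted p = 2.34e-07, but 0.246 with an estimated correlation). In this list young IL27RA− replicates 2 and 3 stood at −0.85 and −0.75 and replicate 1 at −0.07, near old IL27RA− replicate 3 at 0.07. The other old IL27RA− libraries stood at 0.50 and 0.51. The mature B list stood higher (adjusted p = 0.012, and 0.286 with an estimated correlation), with an adjusted p of 0.156 without old IL27RA− replicate 1, the library with Igkc, and 0.0745 without young IL27RA− replicate 1. The count of 99 genes was 271 without young IL27RA− replicate 1, 31 to 41 without any 1 of the old IL27RA− libraries, 25 without the 2 least weighted libraries, and 0 when only these groups were fitted.

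In the IL27RA+ fraction, 51 genes were higher and 12 lower in old cells. Matn4, an extracellular matrix protein gene, had no reads in young libraries and 996 ± 151 normalized counts in old ones, at least 299-fold higher. Rcvrn (174), Gpx8 (166), Spon1 (133) and Guca1b (165) also had no reads in young libraries, and the BMP receptor gene Bmpr1a rose from 0.7 to 374 ± 30. Gimap3, Gimap4, Gimap6 and Gimap7 all fell (−3.76 ± 0.74, −2.80 ± 0.44, −1.25 ± 0.21 and −7.18 ± 1.14, log2). Cxcl12, a chemokine of marrow stroma (219 ± 170 against 0.3), and Mpo, the myeloid granule enzyme (69.1 ± 37.9 against 0), were lower as well, as were Ebi3, Spata13, Lsp1 and Neurl3. Vwf, the von Willebrand factor of platelet-biased stem cells, rose from 975 ± 75.6 to 2291 ± 480.

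Of 37 aged stem cell genes, 15 rose in IL27RA+ cells, 33 adjusted over the list alone (adjusted p = 1.47e-45, and 0.000254 with an estimated correlation). The multipotent progenitor list stood lower, with Lsp1 and Mpo called of 14 members and 4 adjusted over the list alone (adjusted p = 0.00723, but 0.337 with an estimated correlation). Cd53 (1.80 ± 0.45) and Cd34 (−0.83 ± 0.25) did not pass. Of 47 cell cycle genes 44 had a positive difference, with 0 called and 1 adjusted over the list alone, E2f2 (0 against 120 normalized counts; list median 0.80, adjusted p = 0.000507, but 0.578 with an estimated correlation). The progenitor list gave an adjusted p of 0.103 without old IL27RA+ replicate 2, and the cell cycle list 0.413 without young IL27RA+ replicate 3. The cell cycle median was 0.23 without young IL27RA+ replicate 3 and 1.23 without young IL27RA+ replicate 2. Leaving out old IL27RA+ replicate 1, 2 or 3 gave 11, 4 and 4 genes, leaving out young IL27RA+ replicates 2 and 3 or old IL27RA− replicate 2 gave 26, 41 and 31, leaving out young IL27RA− replicate 2 gave 96, and voom on recovered reads called 13. Library weights gave 138 genes.

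The age lists of the fractions overlapped. Of the 76 and 51 genes higher in old cells, 31 were shared, where independent lists would share 0.262 (Fisher's exact p = 6.23e-61), and of the 23 and 12 lower genes 3 were shared (0.0186, p = 7.14e-07). Genes are not independent draws, and both comparisons use the same variance estimate per gene, so these Fisher p-values do not measure chance. The fractions share no library, but the labels do not say whether they came from the same animals. Across 14803 genes, which are not independent replicates, age differences correlated with r = 0.292 (Spearman 0.23), and none of 100 other relabelings exceeded 0.174 in size.

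**Figure D2:**
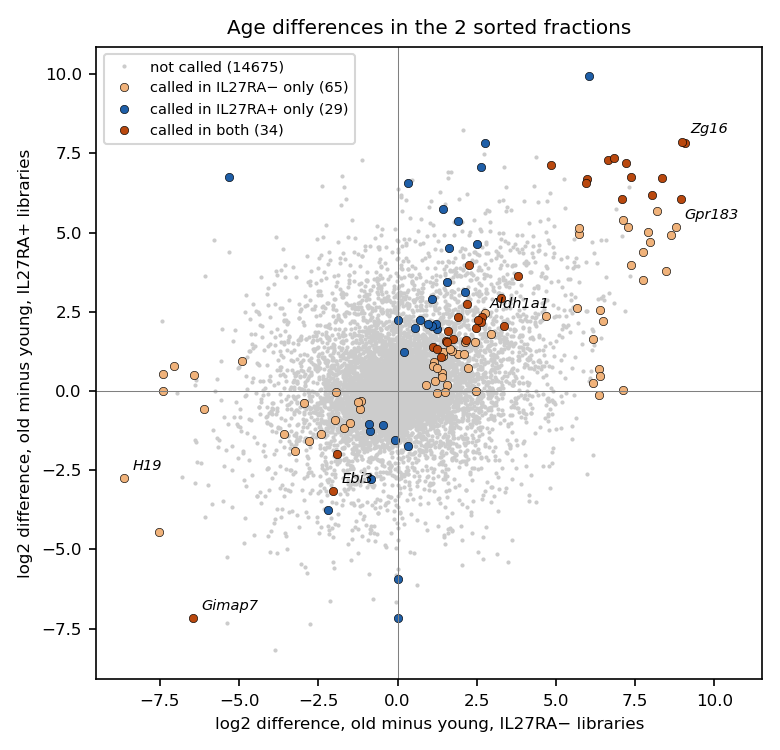
Old minus young log2 differences of 14803 genes in IL27RA− libraries (horizontal axis) and IL27RA+ libraries (vertical axis), with 1 point per gene and n = 3 libraries per group. Genes called in both fractions number 34, genes called in the IL27RA− fraction alone 65 and in the IL27RA+ fraction alone 29. Zg16 and Gpr183 lie at the upper right and Gimap7 at the lower left.

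The sort itself separated few genes in young cells. Vcam1, an adhesion molecule of macrophages and stroma, had 1982 reads in IL27RA+ libraries and 1 in IL27RA− libraries, a depth-adjusted ratio of 3040 (exact 95% counting interval 545 to 120000; limma adjusted p = 0.0386). Vwf stood at 2819 ± 314 normalized counts in IL27RA− and 975 ± 75.6 in IL27RA+ cells (−1.53 ± 0.23, adjusted p = 0.0436). In all 3 genes were called, and the groups of each did not overlap, which chance gives 10% of genes. Values that did not pass were Cxcl12 (0 against 219), the lectin gene Lgals3 (0 against 171), the lysosomal protease gene Lgmn (0.2 against 157), BC030867 (0 against 434), Bmp8a (204 against 0), Neo1 (933 against 116) and Zfp418 (81.6 against 0).

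Macrophage genes in young cells had 1 of 14 called, Vcam1, with 5 higher and 1 lower adjusted over the list alone and a median of 2.45 (adjusted p = 0.000251, but 0.162 with an estimated correlation). The median was 0.23 under the stricter filter, 0.85 without a filter and 1.44 without young IL27RA+ replicate 1. C1qb (18.6 against 597), C1qc (19.9 against 668) and C1qa (45.2 against 909) did not pass over all genes. Several other young lists passed the preset test with no called member. Myeloid genes had a median of 1.00 (adjusted p = 0.000671, but 0.211 with an estimated correlation), with 4 of 22 adjusted over the list alone. Mpo and Hp had no reads in IL27RA− cells and 69.1 and 49.5 normalized counts in IL27RA+ cells. Erythroid genes had a median of 1.30 (adjusted p = 0.00017, but 0.368 with an estimated correlation), and the erythroid factor Gata1 stood at 0 and 167. Both lost the call under the stricter filter. Multipotent progenitor genes had a median of 0.70 (adjusted p = 0.00548, but 0.317 with an estimated correlation), with 2 of 14, Mpo (5.94 ± 1.21) and Cdk6 (1.49 ± 0.33), past the threshold adjusted over the list alone. Cell cycle (0.0146), oxidative phosphorylation (0.0252), ribosomal protein (0.00306) and mitochondrially encoded (0.00011) lists stood higher and glycolysis (0.0334) lower by adjusted p, which became 0.708, 0.742, 0.742, 0.385 and 0.578 with an estimated correlation. Without young IL27RA− replicate 3 the progenitor, cell cycle, oxidative phosphorylation, ribosomal protein and glycolysis lists gave adjusted p of 0.0529, 0.287, 0.290, 0.214 and 0.0607, without replicate 1 the progenitor and glycolysis lists gave 0.0993 and 0.340, and without replicate 2, the least weighted library, the ribosomal protein, oxidative phosphorylation and cell cycle lists gave 0.796 (median 0.07 against 0.23), 0.624 (0.10 against 0.25) and 0.144 (0.53 against 0.90). In the other direction, the ribosomal protein list gave 1.56e-14 (median 0.62) and the oxidative phosphorylation list 8.91e-06 (0.52) without young IL27RA− replicate 1, and the cell cycle list 1.32e-06 (1.74) without young IL27RA+ replicate 3. Over all libraries left out in turn the myeloid median ran from 0.39 to 1.19, the erythroid from 0.79 to 2.42, the progenitor from 0.36 to 0.97 and the glycolysis from −0.41 to −0.15. The cell cycle list also gave 0.252 and 0.398 without young IL27RA+ replicates 1 and 2, the glycolysis list 0.173 and 0.163 and the oxidative phosphorylation list 0.0568 and 0.0599 without young IL27RA+ replicates 2 and 3. Without young IL27RA− replicates 1 and 2 in turn the count of 3 genes became 50 and 11, it was 5 without young IL27RA− or IL27RA+ replicate 3, 1 without young IL27RA+ replicate 2 or old IL27RA+ replicate 1, and 0 without any 1 old IL27RA− library or with voom.

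In old cells the sort separated cell cycle genes. Ncaph had 1447 reads in IL27RA+ and 1 in IL27RA− libraries, a depth-adjusted ratio of 1360 (exact 95% counting interval 244 to 53700; limma adjusted p = 0.00216). Uhrf1 stood at 786 ± 23.1 and 14.6 ± 24.4 normalized counts (7.46 ± 1.08, adjusted p = 0.0295). In all 3 genes were called. All 47 cell cycle genes had a positive difference, with 1 called over all genes, 33 adjusted over the list alone and a median of 3.67 (adjusted p = 1.47e-45, and 0.045 with an estimated correlation). Examples that did not pass over all genes were the thymidylate synthase gene Tyms (1049 against 182), Bub1 (430 against 0) and the mitotic kinase gene Aurkb (1083 against 0.4). Of the macrophage markers 10 of 14 had a positive difference and 4 a negative one, with 0 called, 5 adjusted over the list alone and a median of 2.47 (adjusted p = 0.000126, but 0.139 with an estimated correlation), or 0.32 under the stricter filter and 1.65 without old IL27RA− replicate 2. C1qb (609 ± 404.4 against 0.3), Vcam1 (502 ± 429 against 1.1) and C1qa (925 ± 742 against 30.5) did not pass over all genes.

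The genes lower in old IL27RA+ cells with the smallest p, none of which passed, were Gimap4 (127 against 710 normalized counts), Pik3r1 (2703 against 5519), Cdh22 (0.8 against 76), Spata13 (350 against 948) and Net1 (1120 against 2823). The citron kinase gene Cit (621 against 42.3) and Lgals3 (317 against 1.6) had the smallest p among higher genes that did not pass. Interferon response genes stood lower, with a median of −0.22 and 0 of 60 called over all genes or adjusted over the list alone (adjusted p = 0.000503, but 0.286 with an estimated correlation). Ifitm3 stood at 5236 and 8488 and Ly6e at 10270 and 14310 normalized counts. Mitochondrially encoded (0.000251), ribosomal protein (0.0154) and autophagy and proteostasis (0.0079) lists were lower by adjusted p, which became 0.414, 0.773 and 0.397 with an estimated correlation. Without old IL27RA− replicate 1 the first 2 gave 0.0721 and 0.155, without old IL27RA− replicate 2 and old IL27RA+ replicate 3 the ribosomal list gave 0.385 and 0.924, and without old IL27RA+ replicates 1 and 2 the autophagy list gave 0.0547 and 0.0551. The count of 3 became 24 without young IL27RA− replicate 1, 12 without young IL27RA− replicate 2 or without the 2 least weighted libraries, 6 without young IL27RA− replicate 3, young IL27RA+ replicate 3 or old IL27RA− replicate 1, 2 without old IL27RA− replicate 2 or 3, and 1 without young IL27RA+ replicate 1 or 2 or any 1 old IL27RA+ library. Voom called 0, and library weights gave 86.

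Averaged over age, 23 genes were higher and 5 lower in IL27RA+ cells, and all 28 had the same sign at both ages. Macrophage and mitotic genes were among those higher. Vcam1 (8.02 ± 0.92), the complement genes C1qb (7.72 ± 1.01) and C1qc (5.49 ± 1.00), and Lgals3 (7.30 ± 0.86), the ficolin gene Fcna (5.87 ± 0.83) and the heme oxygenase gene Hmox1 (3.24 ± 0.46) rose. The macrophage and dendritic cell list had 3 of 14 members called, 7 adjusted over the list alone (adjusted p = 8.82e-06, but 0.104 with an estimated correlation). Its median was 2.58, and −0.03 under the stricter filter, 1.07 without a filter and 1.60 with a pseudocount of 8, while 8 of 14 members were positive. The mitotic genes Birc5 (7.69 ± 1.35), Spag5 (7.35 ± 1.02), Fam64a (7.33 ± 1.15) and Ska1 (6.11 ± 0.93) rose too, as did BC030867 and Pkib. The cell cycle list had 1 of 47 called, 27 adjusted over the list alone and a median of 2.31 (adjusted p = 4.27e-27, but 0.104 with an estimated correlation), or 2.24 with groups without reads at the floor.

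Among the 5 genes that fell in IL27RA+ cells were Vwf (−1.03 ± 0.16), the stress-inducible gene Gadd45g (−1.65 ± 0.29), the focal adhesion gene Tenc1 (−1.44 ± 0.26) and the netrin receptor gene Neo1 (−2.20 ± 0.41). Stem cell identity genes were lower as a group, with 0 of 30 called, 2 adjusted over the list alone, 5 positive and a median of −0.23 (adjusted p = 3.18e-06, and 0.0209 with an estimated correlation). Procr, the endothelial protein C receptor of stem cells, stood at 9288 ± 507 and 5819 ± 1209 normalized counts in young and at 13890 ± 1792 and 8356 ± 949 in old IL27RA− and IL27RA+ cells (−0.71 ± 0.14, adjusted p = 0.0565). Hoxb5 (−1.12 ± 0.28) and Sult1a1 (−0.74 ± 0.26) did not pass either. Aged stem cell genes also stood lower, with 2 of 37, Vwf and Neo1, called and 5 adjusted over the list alone (median −0.35, adjusted p = 1.58e-05, but 0.104 with an estimated correlation). The count of 28 was 96 without young IL27RA− replicate 1, 48 without young IL27RA+ replicate 3, and 6 to 18 without any 1 of the other libraries except young IL27RA− replicate 2, and voom called 7.

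**Figure D3:**
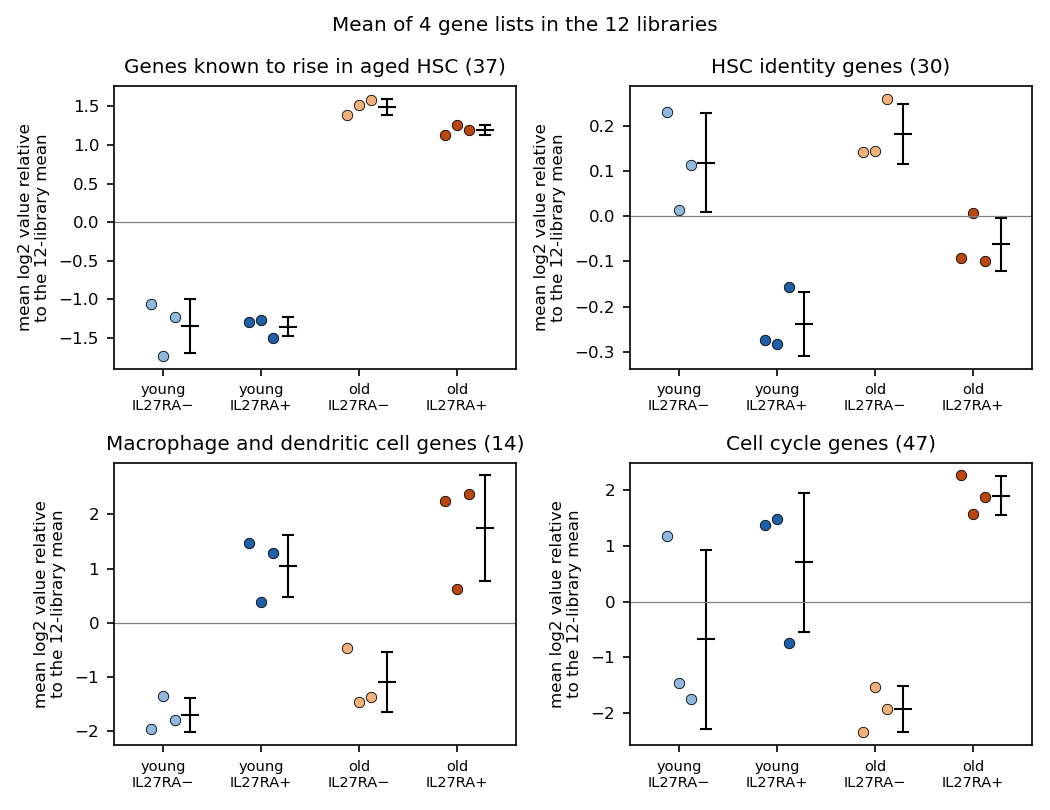
Mean log2 value of the members of 4 gene lists in each library, relative to each gene's mean over the 12 libraries (vertical axes), with points for libraries and bars for the mean ± SD of the 3 libraries of a group. The aged stem cell list separates old (1.13 to 1.59) from young libraries (−1.73 to −1.06), the macrophage list separates IL27RA+ from IL27RA− libraries, and young IL27RA− replicate 1 (1.17) and young IL27RA+ replicate 3 (−0.74) lie apart from their groups in the cell cycle list.

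Whether the IL27RA difference changed with age was tested by the interaction, which called 0 genes with limma (769 at an unadjusted p under 0.05, where 740 are expected) and 0 with voom. The smallest adjusted p was 0.169. Ncaph (7.86 ± 1.29), Guca1b (12.05 ± 1.92) and Rad51c (10.55 ± 1.80) had the smallest p among positive values, and Ccdc157 (−3.99 ± 0.80) and Hs1bp3 (−2.15 ± 0.47) among negative ones. It called 5 genes without young IL27RA− replicate 1, 2 without young IL27RA− replicate 3, 1 without young IL27RA+ replicate 1 or old IL27RA− replicate 3, and 17 with a variance without trend. Across 14803 genes the IL27RA differences of young and old cells correlated with r = 0.168 (Spearman 0.085). Over 100 relabelings r ran from −0.168 to 0.168, and the next largest size was 0.125. Exchanging all labels within an age returns the real grouping with the same size of r. Values of 0.168 in size may therefore not come from other groupings.

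Genes that moved with age and with the sort were few. Vwf, Gadd45g and Ncaph were among 4 genes called in both averaged comparisons, and Vwf and Gadd45g were higher in old and lower in IL27RA+ cells. The fall of Ncaph with age lay in IL27RA− cells, with 829 reads in young and 1 in old libraries. Old IL27RA+ libraries held 1447 reads of it. The 204 genes higher in old cells stood slightly lower in IL27RA+ cells, with a median of −0.13 and 79 of 204 positive (camera p = 5.41e-05, and p = 0.0312 with an estimated correlation). The 70 genes lower in old cells had a median of −0.07 there, with 33 positive (camera p = 0.23, and p = 0.518 with an estimated correlation), and did not mirror the higher ones. Both sets were chosen on the same libraries that then tested them, and their p-values lie outside the 175 adjusted tests. The averaged comparisons share no chance covariance only if library variances are equal, and library weights ran from 0.436 to 1.886. The 204 genes include 28 of the aged stem cell list, already given as lower in IL27RA+ cells. These p-values are therefore no separate support. The averaged age and IL27RA differences correlated with r = −0.034 across genes (Spearman −0.03), and 78 of 100 relabelings gave a value as large.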

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

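The tests of a second macrophage list, of old IL27RA− replicate 1 left out, of progenitors and of exchanged labels were chosen after the results they bear on were seen. In 5 of 25 gene lists the IL27RA+ minus IL27RA− difference itself differed between old and young cells in the preset camera test. For cell cycle genes the adjusted p was 5.91e-16 (median 1.99, 43 of 47 positive, 0.211 with an estimated correlation), and the median was 1.26 without young IL27RA− replicate 1, 1.30 without young IL27RA+ replicate 3 and 3.12 without young IL27RA− replicate 3. For mitochondrially encoded transcripts it was 2.17e-08 (1 of 14 positive, 0.218 with an estimated correlation), and for ribosomal protein genes 2.48e-05 (median −0.38, 3 of 44 positive, 0.647 with an estimated correlation). Young IL27RA− replicates 2 and 3 were the lowest libraries in the mitochondrial list (−0.85 and −0.75) and in the ribosomal protein list (−0.95 and −0.61). For multipotent progenitor genes the adjusted p was 0.0252 (median −0.31, 3 of 14 positive, 0.414 with an estimated correlation). Leaving out young IL27RA− replicate 1 or 3, young IL27RA+ replicate 3, old IL27RA− replicate 3 or old IL27RA+ replicate 2 ended that call (0.161, 0.126, 0.0789, 0.0848 and 0.150, with a median of −0.17 in the last). For oxidative phosphorylation genes it was 0.0459 (median −0.30, 20 of 70 positive, 0.754 with an estimated correlation). None of the 5 passed with an estimated correlation. Without young IL27RA− replicate 2 the ribosomal protein list gave an adjusted p of 0.0567 and the oxidative phosphorylation list 0.552. The oxidative phosphorylation call was also lost without any 1 of the other libraries except young IL27RA− replicate 1, old IL27RA− replicate 3 and old IL27RA+ replicate 1 (0.0590 to 0.290). Over all libraries left out in turn the ribosomal protein median ran from −0.69 to −0.23, the oxidative phosphorylation median from −0.55 to −0.08 and the progenitor median from −0.50 to −0.17.

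Macrophage transcripts such as Vcam1 and C1qb stood higher in IL27RA+ libraries at both ages. The list median of 2.58 lay above all 10000 random lists matched on mean value (percentile 100, central 95% from −0.23 to 0.46). This does not settle whether weaker detection in the IL27RA− libraries plays a part, because the median is unstable. Only 8 of 14 members were positive, with differences of 1.405 to 8.02. The others were Cd74, H2-Aa, H2-Ab1, H2-Eb1, Bst2 and Clec9a, with differences of −1.64 to −0.03 and group means of 127 to 7440 normalized counts. Under the stricter filter the median was −0.03, the value of H2-Eb1, which lies inside the central 95% of the random lists. The list still passed camera there (adjusted p = 0.00708). Macrophages or their fragments sorted with the IL27RA+ cells may be a source: of 25 further macrophage genes, with 5 that were called or named in the IL27RA comparisons left out, 84% were positive (camera p = 1.37e-10, and p = 0.00688 with an estimated correlation), though 3 of the 25 reached 10 normalized counts in all 6 IL27RA− libraries and 2 are in another list. Their levels in young IL27RA+ cells were uneven, with Cd163 at 463, Csf1r at 401 (296 in young IL27RA− cells) and Slc40a1 at 374 normalized counts, but Aif1 at 56.9, Fcgr1 at 18.2, Tyrobp at 13.5, Ms4a7 at 11.9, Fcgr4 at 0.31 and Vsig4 at 0, while in old IL27RA+ cells Fcgr4 stood at 175, Vsig4 at 125 and Ms4a7 at 66.1, against 0, 7.16 and 0 in old IL27RA− cells. Expression by the sorted stem cells cannot be told apart from this, since the called genes' mean Spearman correlation over the 6 IL27RA+ libraries, 0.44, lay between the bounds set in advance, and no gate against macrophages is given in the sources used here.

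Cell cycle genes stood higher in old IL27RA+ than in old IL27RA− libraries. Weaker detection in the old IL27RA− libraries is argued against by a list median above all 10000 matched random lists (percentile 100). The library with immunoglobulin transcripts is argued against as the cause, since without it the median was 3.25 against 3.67. Multipotent progenitors in the IL27RA+ sort cannot be told apart, because their list's median of 0.01 decides nothing with members going both ways. A difference between the sorted fractions themselves stays open and was not tested.

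Igkc in old IL27RA− replicate 1 stood at 312300 normalized counts. Plasma cells in that well could be the source: of 18 other plasma cell genes with reads, 8 were highest there, where 1.5 are expected (exact one-sided binomial p = 4.73e-05). Genes of 1 library are not independent draws, so this p-value does not measure chance. Igj stood at 60227, Prdm1 at 597 and Pou2af1 at 387 normalized counts in that library, but Sdc1 at 2.9, the lowest of the 12 libraries, Irf4 at 12.5 and Xbp1 at 4423 (3736 to 13292 in the others). Carry-over between wells was not tested, nor was any biological explanation. The same library, which 1 label calls young, stood at 1.39 in the aged stem cell list, where the other old libraries stood at 1.13 to 1.59 and the young ones at −1.73 to −1.06.

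Other splits of the same libraries tested whether chance alone gives as many calls. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. For IL27RA in young cells the real split called 3 genes and the highest other 4, and 4 of the 10 called as many as the real one. For IL27RA in old cells the real split called 3 and the highest other 0, for age in IL27RA− cells 99 and 8, and for age in IL27RA+ cells 63 and 0, so 1 of the 10 called as many. The splits treat libraries as separate units, so they cannot decide on a chance difference between animals, which the labels do not tell apart. For the averaged age comparison 1 of 100 splits called as many (274, highest other 2), a share under 0.05. For the averaged IL27RA comparison 2 of 100 did (28, highest other 54), also under 0.05. For the interaction the real split called 0 (highest other 1), so 100 of 100 call as many by construction, and this count decides nothing.

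The split with 54 calls exchanged young IL27RA− replicate 1 with young IL27RA+ replicate 3 and left the old libraries as they were, which points to a structure of these samples. The same libraries lie apart in the cell cycle list, at 1.17 and −0.74. An exchange of their labels could give this, but the mean macrophage list value was 3.24 higher (log2) in young IL27RA+ replicate 3 than in young IL27RA− replicate 1, as the labels have it.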

How the results depend on the processing

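The voom fit and the fit without the 2 least weighted libraries were chosen after the data were seen, the others before. Counts of called genes depended on the fit. Over 132 named called genes and their 2992 alternatives, 2279 kept direction and call, 713 lost the call and 0 reversed. These genes were chosen for groups that did not overlap or signs that matched, so reversals were unlikely from the start. The fit of only the groups compared was not among these alternatives. Some list medians turned. The macrophage median in the averaged IL27RA comparison went from 2.58 to −0.03 under the stricter filter. The ribosomal protein median in old cells went from −0.15 to 0.007 without old IL27RA+ replicate 3. The main results had 298 alternatives, of which 204 stayed the same, 52 were weaker, 31 stronger and 11 reversed. The reversals were of the Il27ra difference and of the correlation of averaged differences, both near 0. Where not stated otherwise, the cause was not tested.

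For IL27RA in young cells (3 genes) the count was 8 without the low-value filter, 1 with the stricter one or quantile normalization, 27 without a variance trend, 6 with a pseudocount of 8, and 0 with library weights, voom or only the groups compared. In old cells (3) it was 5 without the filter, 25 without a trend, 86 with weights, 10 with a pseudocount of 8, 0 with voom, 12 without the 2 least weighted libraries and 29 with only the groups compared. For age in IL27RA− cells (99) it was 64 with no or the stricter filter, 25 without the 2 libraries and 0 with only the groups compared, and in IL27RA+ cells (63) 138 with weights, 13 with voom and 37 with only the groups compared. For the averaged IL27RA comparison (28) it was 14 without the filter, 8 with the stricter one, 49 without a trend, 45 with weights, 7 with voom and 18 without the 2 libraries. The interaction called 17 without a trend. Of 175 list tests 51 were called, 5 with an estimated correlation and 23 with fry. The correlation of averaged age and IL27RA differences was 0.032 with voom.

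Leaving out each library in turn gave 0 to 50 genes for IL27RA in young cells, 1 to 24 in old cells, 31 to 271 for age in IL27RA− cells, 4 to 96 in IL27RA+ cells, 6 to 96 for averaged IL27RA, 140 to 431 for averaged age, 0 to 5 for the interaction and 41 to 56 lists. It moved the Il27ra difference from −0.468 to 0.101 in young and from −0.249 to 0.052 in old cells, and the correlation of averaged differences from −0.146 to 0.156. The correlation between the ages of the IL27RA difference was 0.133 to 0.193, and that between the fractions of the age difference 0.252 to 0.291. Fits that leave 2 libraries in a group take their spread from all groups.

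Whether replicate numbers pair the libraries stays open. Over 18 pairs with the same number the correlations of deviations from group means were −0.054 to 0.106, 1 over 0.1. Of the libraries, 2 correlated best with their own number. IL27RA− and IL27RA+ libraries of the same number and age correlated with 0.106, 0.028 and 0.017 in young cells. In old cells these values were 0.031, 0.004 and 0.096. With different numbers at the same age they ran from −0.068 to 0.038. With the replicate block 0 genes were called for IL27RA in young cells, 2 in old cells, 99 and 43 for age in the fractions, 20 and 307 for the averages and 53 lists. The depth of 11669083 to 24153167 reads in 50 cells leaves genes near the floor of 3 reads undecided.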

Other observations

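Averaged over the fractions, Cd74 and H2-Aa, genes of antigen presentation by MHC class II, rose with age. Cd74, the invariant chain, stood at 1948 ± 820 in young and 6987 ± 1465 normalized counts (SD, n = 3) in old IL27RA− cells, and at 2182 ± 1128 and 4649 ± 1639 in IL27RA+ cells (averaged difference 1.54 ± 0.29, limma adjusted p = 0.0131), and the averaged difference of H2-Aa was 1.58 ± 0.35 (adjusted p = 0.0311). H2-Eb1 (2.06 ± 0.50) and H2-Ab1 (1.68 ± 0.48) did not pass. These 4 genes had the smallest p in the macrophage and dendritic cell list, which stood higher in old cells (2 of 14 called, 5 adjusted over the list alone, adjusted p = 0.0252, but 0.369 with an estimated correlation) and gave 0.0991, 0.0882 and 0.0692 without old IL27RA− replicate 1, young IL27RA− replicate 1 and old IL27RA+ replicate 3. Cd74 and H2-Aa were also the 2 called members of the 7 in the mature B list. Averaged over the fractions, that list stood higher in old cells (median 1.58, camera adjusted p = 0.00949, but 0.285 with an estimated correlation). Without old IL27RA− replicate 1 its median was 0.73 (adjusted p = 0.0334), and the adjusted p was at most 0.0417 without any 1 library. The protease gene Prtn3, a myeloid granule gene, rose from 4064 ± 448 and 4438 ± 681 to 10690 ± 2173 and 9283 ± 1506 (adjusted p = 0.000439), while Mpo was called lower in old IL27RA+ cells. Socs3, a feedback inhibitor of cytokine signalling, rose from 142 and 155 to 1869 and 997 (3.72 ± 0.72, adjusted p = 0.0152), opposite to Socs2.

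Of the list of IL27 and TNF signalling genes, Ebi3 and Socs3 were called with age, in opposite directions, and the list was not called with age (adjusted p = 0.797). In IL27RA+ cells it stood lower (median −0.16, adjusted p = 0.0193, but 0.162 with an estimated correlation), with 0 of 21 called, and the lowest p for Ets1 (−1.05 ± 0.35). The camera adjusted p was 0.0524 and 0.0595 without young IL27RA− replicates 1 and 3, and 0.0776 with quantile normalization. Without old IL27RA− replicate 3 the median was −0.09. Lymphoid priming, NF-kB, immediate early, CDK inhibitor, p53, epigenetic regulator, T and NK cell, stroma and endothelium, and stress RNA lists were called in no comparison at the preset correlation. With fry the stroma and endothelium list was called higher in IL27RA+ cells in the young (adjusted p = 0.0297) and averaged comparison (0.042), and the myeloid list, not called by camera with age, lower in old cells in the IL27RA+ fraction (0.0142) and averaged (0.0446). In the averaged age comparison Satb1 (−3.36 ± 0.83) and Ltb (−0.83 ± 0.21) of the lymphoid list did not pass.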
